A study of Mus musculus with 6 samples.

How the data were processed

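RNA from heart muscle cells of wild-type mice was measured by RNA sequencing in 6 libraries. Per the labels' protocols, mice at postnatal day 21 received daily injections of α-ketoglutarate (AKG, also called 2-oxoglutarate, an intermediate of the tricarboxylic acid cycle) at 300 mg per kg per day, or of phosphate-buffered saline as the Control, for 2 weeks. The heart muscle cells were isolated by Langendorff perfusion, in which an enzyme solution is run through the coronary vessels, and libraries were made from mRNA. The labels name day 21 for the injected animals and for the animals from which cells were taken, and the age at each end of the injections was not given in the sources used here. Each group held 3 libraries. The labels did not say whether a library came from 1 mouse or from a pool, so the p-values measured only the spread between these libraries.

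The authors deposited 1 table of 22063 genes with an estimated count and an FPKM value per gene and library. The deposited counts were whole numbers, and 60 values of 0 counts stood beside an FPKM above 0, as rounded expected counts would. FPKM values (fragments scaled to transcript length and library total) were made by the authors and deposited beside the counts. The authors' deposited log2 fold change was the ratio of the group means of FPKM, and a p-value and a false discovery rate were deposited with it. The submitters' processing notes named HISAT2 2.1.0, RSEM 1.2.19 and DESeq2 1.20.0. The role of each tool, the genome build and the annotation were not given in the sources used here, and the table held no coordinates, so none are printed. Because FPKM is scaled to the total of each library, a fall of very abundant transcripts raises the FPKM of all other genes. The median difference between the authors' log2 fold changes and those computed here from counts was 0.44, a 1.36-fold shift.

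Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were left out with edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 13117 genes, and libraries were scaled by the trimmed mean of M-values (TMM). AKG was compared with Control by edgeR's quasi-likelihood test with robust dispersion estimates, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Every adjusted p of a gene came from this test unless another tool is named. Each SE was worked back from this test, as the size of the log2 fold change divided by the square root of the F statistic. It is not a standard error estimated by the fit itself. Levels are given as counts scaled to the TMM-scaled library total (CPM), as mean ± SD over 3 libraries. A rise or fall is therefore relative to the bulk of genes and not an amount per cell. Shares of counts were compared by exact two-sided permutation tests, which cannot give a p under 0.1 for 3 libraries against 3. Totals ranged from 14402876 to 17797368 counts per library, and a floor of 3 counts corresponded to 0.166 to 0.221 CPM. For genes with 1 to 3 counts in a group, the ratio is given with an exact 95% binomial interval, which covers counting error only. Rows without a symbol (30) held 3.95e-05% of the counts and were not named.

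Before the data were examined, 31 gene lists, the comparison, the alternatives and the rule for named genes were fixed. The rule took, among genes past the threshold whose groups did not overlap and whose mean CPM was at least 1, the 10 largest rises, the 10 largest falls and the 5 smallest p-values in each direction, up to 4 members of each described list by smallest p, and 12 genes given whatever they did. A few genes that the rule named are not reported here. Sln, Myl7, Myl4, Bmp10, Mybphl, the Y-linked genes, Tap1, Gbp2 and the genes of the imprinted and glucocorticoid lists in the closing part were chosen after values had been seen, and so were list members beyond the 4 with the smallest p. Lists were tested with camera (limma 3.58.1), which asks whether a list moved relative to all other genes, with a preset correlation between genes of 0.01, and again with a correlation estimated per list. The fry test, which asks whether a list moved on balance in either direction, was a further alternative. Pathway and ontology terms of the deposited table with 15 to 500 tested genes were tested in the same way.

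Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1 (genes at FPKM 1 or more in 3 libraries), the replicate number as a block, and leaving out each library. After the data had been seen, 5 more were added: the level of atrial transcripts as a covariate, the level of Y-linked transcripts as a covariate, AKG 2 alone against the 3 Controls, total counts as the scaling, and the table without mitochondrially encoded genes. The atrial covariate was the mean log2 CPM of Sln, Myl7, Myl4, Bmp10 and Mybphl. Transcript length and GC content came from the longest transcript per gene of GENCODE M21, matched by gene identifier for 99.9% of tested genes. The tests were run on simulated counts for AKG against Control, drawn 12 times over about 13022 genes with 200 changed in each draw. Of genes changed 1.5-fold, 2-fold and 4-fold, edgeR recovered 59.2%, 84.6% and 98% in this order. In the simulation 9.79% of calls were false, above the 5% aimed for, and 4.81% of unchanged genes had an unadjusted p under 0.05. In the data 50.24% of tested genes were called, far more than were changed in the simulation. The false share and the recovery may therefore differ in the data. Of 100 random lists of unchanged genes in each draw, 0% had a camera p under 0.05, where genes were simulated as independent of each other.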

Results

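The transcriptome of isolated mouse heart muscle cells was compared between mice injected with AKG and mice injected with saline, with 3 libraries in each group. The comparison asked which transcripts changed with a treatment that the study linked to division of heart muscle cells. The Control libraries held 17660063, 17797368 and 16241120 counts and the AKG libraries 15315236, 14402876 and 14783678. The first principal component held 71.7% of the variance and separated the groups.

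Heart muscle cell preparations from AKG-treated mice held far more transcript of Myh7 and Tnni1, contractile genes of the fetal heart. They held less of the genes for mitochondrial respiration, and mitotic genes were higher. The preparations also held transcripts of other cell types, so these changes cannot be read as changes within heart muscle cells. Myh7, the slow myosin heavy chain of the fetal ventricle, rose from 21.03 ± 2.14 CPM in Control to 1707 ± 258 CPM after AKG (mean ± SD over 3 libraries). Myh6, the adult cardiac myosin heavy chain, fell from 27743 ± 1091 to 12427 ± 1768 CPM. Of 13117 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 3281 were higher and 3309 lower after AKG at an adjusted p under 0.05. Changes of at least 2-fold were found for 616 higher and 803 lower genes. The 3 values of one group lay wholly above those of the other for 59.2% of tested genes, where chance gives 10%. The split depended on the scaling: with total counts as the scaling 7431 genes were higher and 1196 lower, since the median log2 fold change of all genes was then 0.45 instead of 0.00. Limma on log2(FPKM + 1) gave 6732 and 1068, and 1698 higher and 398 lower genes changed at least 2-fold in the authors' deposited FPKM ratios at a false discovery rate under 0.05. All changes below are relative to the bulk of genes.

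Among the 10 largest rises, Myh7 (log2 fold change 6.34, SE 0.145) and Tnni1, the slow skeletal troponin I of the fetal heart (6.26, SE 0.477), stood at high levels, with adjusted p = 1.65e-11 and 0.000472 in edgeR's quasi-likelihood test. Tnni1 went from 6.71 ± 4.31 to 517 ± 86.7 CPM. Plppr1 had 1 count over the Control libraries and 159 over the AKG libraries, a ratio of 136 with a counting interval of 24 to 5400. The fetal RNA-binding protein gene Igf2bp1 rose by 3.97 on the log2 scale, the acyl-CoA synthetase gene Acss3 by 3.66 and the transporter gene Slc10a6 by 3.64, and Hif3a rose from a mean of 2.90 CPM. Dusp26 (4.09), Aldoc (3.78) and Ngp (3.77) also rose, each from a Control mean under 0.2 CPM. Hif3a and Slc10a6 varied widely within the AKG group, at 40.3 ± 20.3 and 7.42 ± 4.07 CPM. Among the smallest p-values of the rises, beside Myh7, were those of Ccn2, a matricellular growth factor gene (24.99 ± 2.08 to 181 ± 12.3 CPM), the imprinted gene Mest (83.4 ± 8.22 to 431 ± 25.3 CPM) and Serpinb6b.

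Among the 10 largest falls, Lypd8l had 250 counts over the Control libraries and 1 over the AKG libraries, a ratio of 292 with a counting interval of 52 to 11600. Rtn4r, a receptor for myelin proteins, fell from 25.2 ± 5.35 to 0.601 ± 0.136 CPM (edgeR quasi-likelihood adjusted p = 3.1e-09). The tubulin gene Tuba8 fell from 127 ± 1.64 to 8.34 ± 2.55 CPM and the matrix protein gene Hmcn2 from 134 ± 9.62 to 9.23 ± 3.4 CPM. Pcp4, Pnpla3, Plaat1, Mgl2, Cpn2 and Sec14l5 completed the 10, with log2 fold changes of -5.15, -5.14, -4.57, -4.46, -4.02 and -3.79. The smallest p-values among the falls belonged to Tuba4a (351 ± 26.7 to 53.7 ± 1.62 CPM), the small heat shock protein genes Hspb6 (465 ± 47.6 to 69.1 ± 5.15 CPM) and Hspb8 (219 ± 13.2 to 55.7 ± 1.93 CPM), Trim7 and the lipid droplet gene Fitm2.

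**Figure D1:**
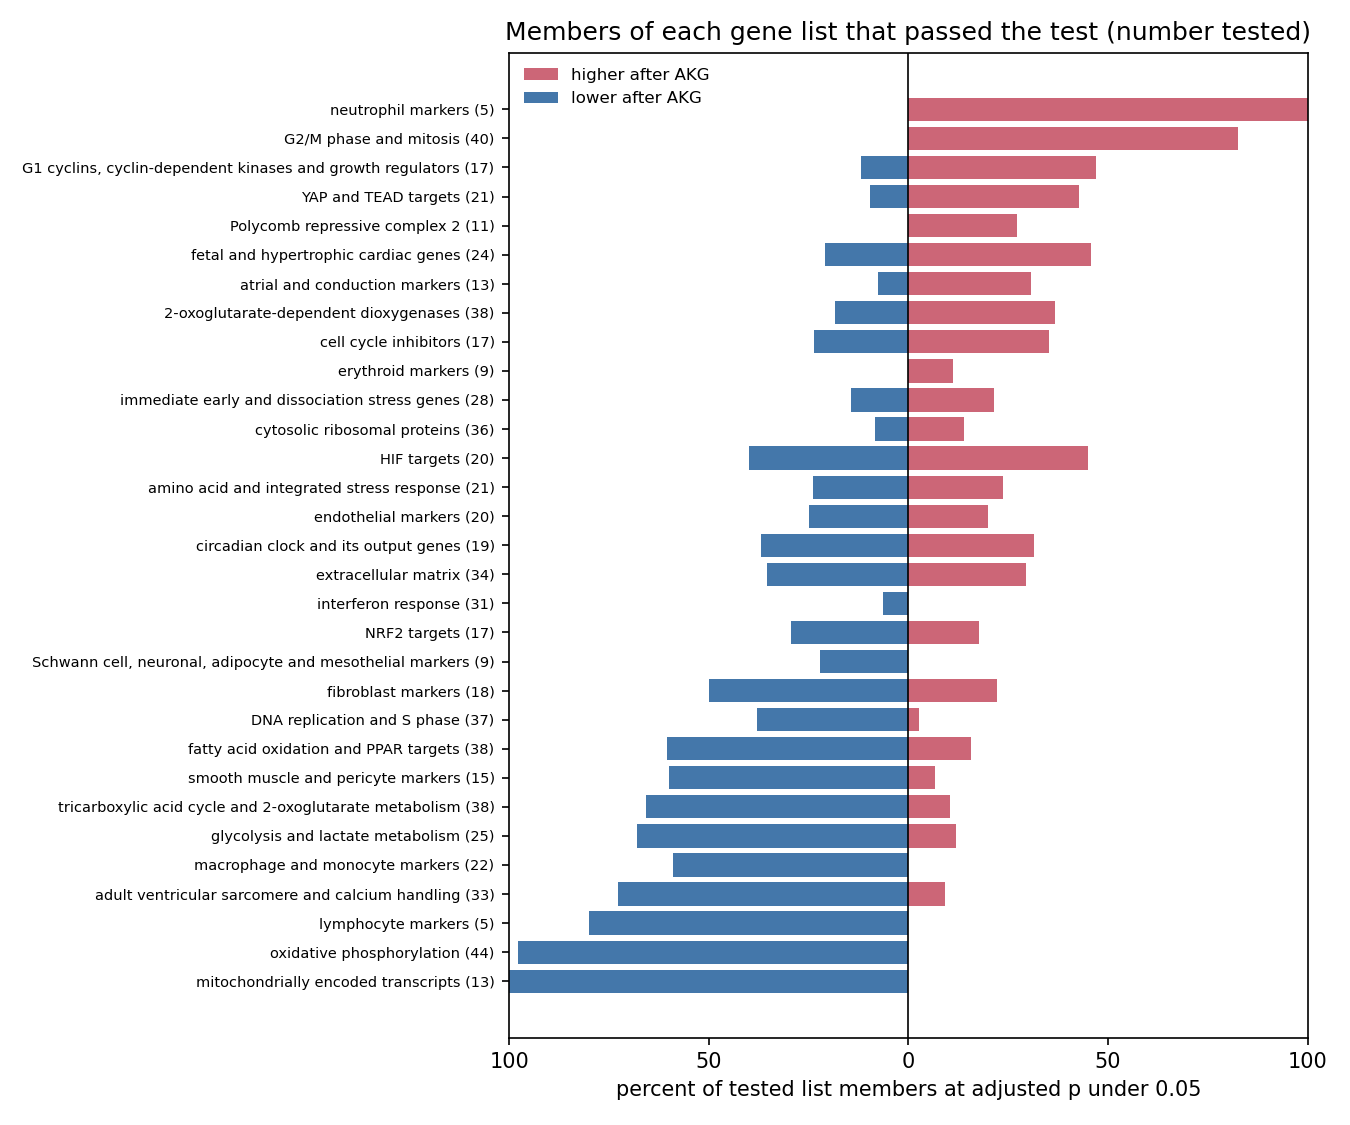
Horizontal bars show, for each of the 31 gene lists, the percent of tested members that were higher (right) or lower (left) after AKG at an edgeR quasi-likelihood adjusted p under 0.05, with the number tested in parentheses. All 13 mitochondrially encoded transcripts and 43 of 44 oxidative phosphorylation genes were lower, and 33 of 40 G2/M genes were higher.

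Genes of the G2 and M phases of the cell cycle were higher after AKG while genes of DNA replication were not. Of 40 G2/M genes, 33 rose and 0 fell (34 rose when adjusted over the list alone), with a median log2 fold change of 0.83. With total counts as the scaling all 40 were higher. The cyclin gene Ccnb2 rose from 8.69 ± 1.15 to 23.5 ± 2.58 CPM, the kinetochore motor gene Cenpe from 11.03 to 25.5 CPM and the proliferation marker Mki67 from 70.1 ± 9.37 to 130 ± 9.16 CPM. Ccnb1 rose by 1.04, Top2a by 0.83 and Cdk1 by 0.33 on the log2 scale. Of 37 DNA replication and S phase genes, 14 fell and 1 rose, and the counts were the same when adjusted over the list alone. The helicase genes Mcm2 (14.7 to 5.51 CPM) and Mcm3 (15.8 to 7.40 CPM) and the clamp gene Pcna fell, and Mcm7 rose from 16.3 to 28.3 CPM. The median of this list was -0.35, and 0.09 with total counts as the scaling, where 9 members were higher and 4 lower and the list passed camera as lower (adjusted p = 0.0156). By camera the G2/M list was past the threshold (adjusted p = 1.34e-08, and 0.554 with an estimated correlation) and the S phase list was not (0.0801). With the level of atrial transcripts as a covariate 20 of the G2/M genes were higher, and the list still passed camera. Over all genes the higher calls fell from 3281 to 2158 in that fit, so fewer calls need not mean smaller changes.

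Regulators of the cell cycle moved both ways. Of 17 G1 cyclin, kinase and growth regulator genes, 8 rose and 2 fell. The growth factor receptor gene Igf1r rose from 38.2 to 88.4 CPM and Ccnd1 from 38.2 ± 5.33 to 73.0 ± 8.1 CPM, Erbb2 rose by 0.74 and Mycn fell from 15.2 to 4.54 CPM. Of 17 cell cycle inhibitor genes, 6 rose, among them Rbl2 (28.7 to 57.6 CPM), and 4 fell, among them Ccng1 (359 to 156 CPM) and Gadd45a (7 and 4 when adjusted over the list alone). Neither list was past the camera threshold (adjusted p = 0.0706 and 0.812). With total counts as the scaling 14 of the G1 genes were higher and 1 lower, and 13 of the inhibitor genes were higher and 3 lower.

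Fetal and hypertrophic cardiac genes were higher on balance. Of 24 tested, 11 rose and 5 fell (12 and 5 when adjusted over the list alone), with a median of 0.53. Besides Myh7 and Tnni1, the stress-responsive titin partner Ankrd1 rose from 310 ± 30.9 to 954 ± 74.5 CPM, the fetal growth factor Igf2 from 278 ± 39 to 828 ± 81.4 CPM and the natriuretic peptide gene Nppa from 120 ± 29.6 to 558 ± 142 CPM. Nppb had a log2 fold change of 0.76 with an edgeR quasi-likelihood adjusted p of 0.032, which rose to 0.085 without Control replicate 1, 0.0829 without Control replicate 2, 0.0928 without AKG replicate 2 and 0.138 without AKG replicate 3. The slow skeletal troponin T gene Tnnt1 fell from 31.2 to 15.9 CPM. The camera adjusted p of the list was 0.000261, and 0.38 with an estimated correlation. Atrial transcripts moved with this group in 2 of the 3 AKG libraries. Sln stood at 42.8 and 28.8 CPM in AKG 1 and AKG 3, at 0.186 CPM in AKG 2 and at 0.476 CPM or less in the Controls. Myl7 stood at 138, 88 and 1.12 CPM in these AKG libraries and at 4.15 CPM or less in the Controls. With AKG 2 alone 9 members of the fetal list were higher and its median was 0.03, and Nppa had a log2 fold change of 1.92 with an edgeR quasi-likelihood adjusted p of 0.0618. Myh6 and Myh7 are close in sequence, so the exact split of their reads is uncertain, but 21.03 CPM of Myh7 beside 27743 CPM of Myh6 in Control leave no room for misassigned Myh6 reads as the source of the rise.

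**Figure D2:**
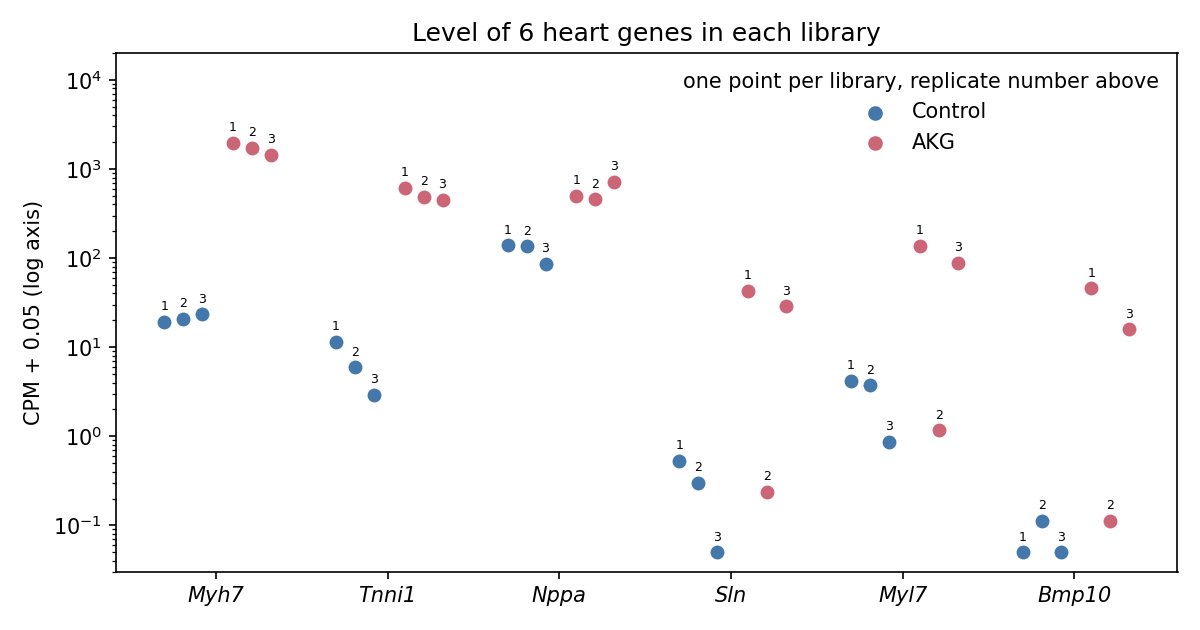
Points show the CPM (plus 0.05, log axis) of 6 genes in each Control and AKG library, with the replicate number above each point. Myh7, Tnni1 and Nppa were higher in all 3 AKG libraries, and the atrial genes Sln, Myl7 and Bmp10 in AKG 1 and AKG 3 but not in AKG 2.

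Of 13 atrial and conduction markers, 4 rose, Nppa, Gja5 and Dkk3 among them, and the pacemaker channel gene Hcn4 fell. The list had a median of 0.89 and a camera adjusted p of 0.0801. It depended on single libraries: without AKG replicate 2, 10 of 15 tested markers were higher and 0 lower, with a median of 2.35, and with AKG 2 alone 2 of 13 were higher, with a median of 0.04. The list had 9 higher and 0 lower markers with total counts as the scaling, 8 and 1 without robust dispersion estimates and 7 and 1 with DESeq2. Y-linked transcripts (Ddx3y, Uty, Kdm5d and Eif2s3y) summed to 168, 0.311 and 176 CPM in Control 1, 2 and 3 and to 89.2, 50.4 and 39 CPM in AKG 1, 2 and 3, so the sexes of the mice were not balanced between the libraries. Every AKG sum lay between that of Control 2 and those of the other Controls. The AKG libraries may therefore each hold mice of both sexes, which was not tested.

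Transcripts of the respiratory chain were lower after AKG. Of 44 nuclear genes of oxidative phosphorylation, 43 fell and 0 rose, with a median of -1.04, and the count was the same when adjusted over the list alone. The complex I genes Ndufb3 (108 ± 9.6 to 33.5 ± 2.43 CPM), Ndufs8 (227 to 78.6 CPM) and Ndufb10 (385 to 131 CPM) and the cytochrome c gene Cycs (765 to 257 CPM) had the smallest p-values. All 13 mitochondrially encoded transcripts fell, with a median of -1.06, and their share of counts was 40.8 ± 2.44% in Control and 29.1 ± 2.99% after AKG (SD, n = 3, exact two-sided permutation p = 0.1, the smallest possible). The medians were -0.59 and -0.62 with total counts as the scaling. By camera both lists were past the threshold (adjusted p = 2.11e-42 and 1.91e-10), with 0.38 and 0.515 as the adjusted p with an estimated correlation. Among the deposited pathway terms, 32 of 317 were past the threshold, 29 of them lower, and the term for oxidative phosphorylation had 107 of 123 genes lower. None of the terms was past the threshold with an estimated correlation (smallest adjusted p = 0.479). Among ontology terms 54 of 1620 processes, 34 of 368 components and 9 of 460 functions were past it, and none with an estimated correlation (smallest 0.785, 0.556 and 0.612).

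**Figure D3:**
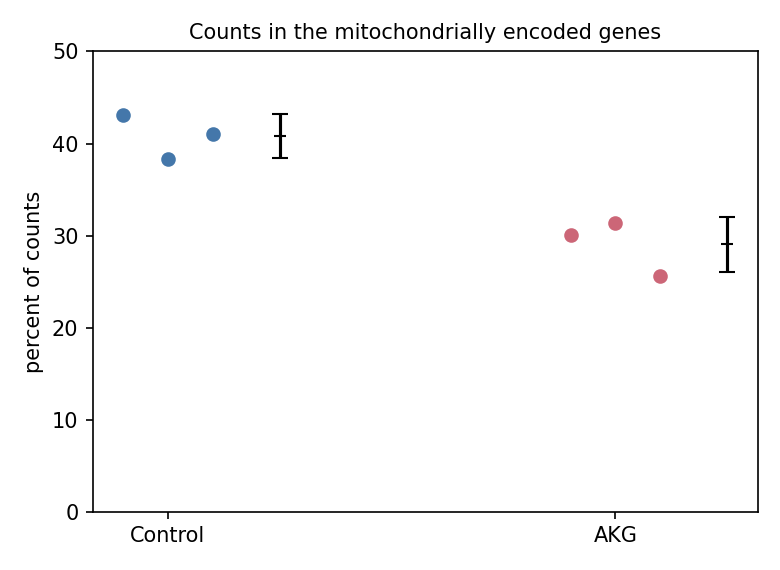
Points show the percent of counts in mitochondrially encoded genes in each library of both groups, with the mean and SD of 3 libraries beside them in black. The Control libraries lay between 38.3% and 43.2% and the AKG libraries between 25.7% and 31.4%.

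Genes of the pathways that feed the respiratory chain fell as well. Of 38 genes of the tricarboxylic acid cycle and of 2-oxoglutarate metabolism, 25 fell and 4 rose, with a median of -0.65. The 2-oxoglutarate carrier Slc25a11 fell from 261 to 124 CPM, Sdhc from 303 to 160 CPM, Idh3a from 512 to 263 CPM and Sdhb from 540 to 245 CPM. Of 25 glycolysis genes, 17 fell and 3 rose. Hexokinase Hk2 fell from 152 to 50.8 CPM and the glucose transporter Slc2a4 from 167 to 60.7 CPM, and the pyruvate dehydrogenase kinase Pdk1 rose from 59.3 to 125 CPM. Of 38 fatty acid oxidation genes, 23 fell, among them Cpt2 (179 to 81.1 CPM) and Etfb (504 to 229 CPM), and 6 rose, among them Acot1 (23.7 to 109 CPM). These 3 counts were the same when adjusted over the list alone. The camera adjusted p was 3.63e-07, 1.78e-06 and 0.0335 for the 3 lists in this order, and 0.554, 0.492 and 0.58 with an estimated correlation. With total counts as the scaling 11 genes of the tricarboxylic acid cycle list were higher and 16 lower (median -0.21), and 6 glycolysis genes were higher and 10 lower (median -0.09). The fatty acid list then had 15 higher and 7 lower genes and a median of 0.07, and no longer passed (camera adjusted p = 0.507). This list did not pass with the replicate block or the atrial covariate either, nor in every case with a library left out.

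Genes of the adult contractile apparatus fell. Of 33 adult sarcomere and calcium handling genes, 24 fell and 3 rose, with a median of -0.69. The cardiac actin gene Actc1 fell from 11995 to 2996 CPM, the tropomyosin gene Tpm1 from 9317 to 2945 CPM and the calcium-binding protein gene Hrc from 391 to 121 CPM, and the M-band gene Myom2 rose from 478 to 1525 CPM. The camera adjusted p was 1.15e-10, and 0.38 with an estimated correlation. Of 21 targets of YAP and TEAD, the transcription factors at the end of the Hippo pathway, 9 rose, led by Ccn2 and Ankrd1 and followed by Amotl2 (64.1 to 95.0 CPM), and 2 fell (10 and 3 when adjusted over the list alone). Their camera adjusted p was 0.00392, and 0.492 with an estimated correlation. With total counts as the scaling 7 sarcomere genes were higher and 17 lower, and 17 YAP and TEAD targets were higher and 1 lower. With the atrial covariate 5 of these targets were higher and the list still passed camera, in a fit where higher calls over all genes fell from 3281 to 2158.

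Enzymes that use 2-oxoglutarate as a substrate did not move as a group. Of 38 dioxygenase genes, 14 rose and 7 fell (the same when adjusted over the list alone), with a camera adjusted p of 0.619. The prolyl hydroxylase genes Egln3 (58.2 to 17.1 CPM), P4ha2 (29.5 to 11.5 CPM) and P4ha1 (40.0 to 21.3 CPM) fell, and the histone demethylase gene Kdm5b rose from 27.8 to 54.0 CPM. The histone H3 lysine 27 demethylase gene Kdm6b stood at 61.4 ± 2.65 and 67.5 ± 5.4 CPM, with an adjusted p of 0.163 in edgeR's quasi-likelihood test, and 0.0475 without AKG replicate 2. Kdm6a stood at 24.6 ± 10.4 and 42.2 ± 4.08 CPM (0.09, and 2.01e-05 without Control replicate 2, the library that lacked Y-linked transcripts). Control 2 held 36.6 CPM of Kdm6a, beside 17.6 and 19.7 CPM in Control 1 and Control 3. Those Controls also held more Y-linked transcript than any AKG library, so sex and AKG cannot be told apart for this gene. Of 11 genes of the Polycomb repressive complex, 3 rose: the methyltransferase genes Ezh1 (30.7 to 58.7 CPM) and Ezh2 (11.2 to 18.1 CPM), and Suz12. The list had a camera adjusted p of 0.344. With total counts as the scaling 25 dioxygenase genes were higher and 4 lower, and 9 Polycomb genes were higher. With the atrial covariate 7 dioxygenase genes were higher and 5 lower. Calls over all genes also fell in that fit, from 3281 to 2158 higher and from 3309 to 2250 lower, so this need not mean smaller changes.

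Markers of other cell types were lower, mixed or mostly not past the threshold, except for those of neutrophils. Of 18 fibroblast markers, 9 fell, led by Pi16 (74.8 to 21.1 CPM) and Mfap5 (92.6 to 32.9 CPM), and 4 rose. Of 15 smooth muscle and pericyte markers, 9 fell and 1 rose. Of 22 macrophage and monocyte markers, 13 fell and 0 rose, among them C1qa (29.2 to 11.5 CPM). Of 15 lymphocyte markers only 5 had enough counts to be tested, and 4 of these fell. Without Control replicate 3, and also with the Y-linked covariate, 8 macrophage markers were lower. Of 20 endothelial markers, 4 rose and 5 fell (2 and 3 when adjusted over the list alone, and also without Control replicate 1 or Control replicate 3). Of 13 neutrophil markers only 5 had enough counts to be tested, and these rose, from low levels such as 0.292 to 3.44 CPM for S100a9. Ngp, S100a9, Ltf and Mmp9 had only 7, 13, 8 and 11 counts over the Control libraries. They passed the count filter only through the AKG libraries, so a rise was favoured in advance. Without the low-count filter 6 of 10 neutrophil markers were higher and 0 lower, with a median of 2.27. The camera adjusted p was 0.00795 for fibroblast, 0.0257 for smooth muscle, 0.00413 for macrophage, 0.0741 for lymphocyte, 0.689 for endothelial and 0.013 for neutrophil markers. With an estimated correlation it was 0.58, 0.548, 0.58, 0.554, 0.927 and 0.515. With total counts as the scaling the medians of the fibroblast, smooth muscle and endothelial lists were 0.07, 0.07 and 0.34 instead of -0.38, -0.39 and -0.10, and 6, 4 and 13 members were higher and 4, 3 and 1 lower. The macrophage list then had 1 higher and 6 lower members, and the smooth muscle and neutrophil lists no longer passed (camera adjusted p = 0.0572 and 0.0839). The smooth muscle list did not pass with the atrial covariate either (camera adjusted p = 0.0584). Of 9 erythroid markers 1 rose and of 9 Schwann cell, neuronal, adipocyte and mesothelial markers 2 fell, with camera adjusted p of 0.634 and 0.553, and with total counts 8 and 3 of them were higher.

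The remaining lists were not past the camera threshold. Of 20 targets of the hypoxia-inducible factors, 9 rose (Mxi1, 33.1 to 76.0 CPM) and 8 fell (Higd1a, 65.9 to 19.4 CPM), and of 34 extracellular matrix genes 10 rose (Fn1, 209 to 417 CPM) and 12 fell (Col15a1, 282 to 121 CPM). In 21 genes of the amino acid and integrated stress response 5 rose and 5 fell, in 17 NRF2 targets 3 rose and 5 fell, and in 28 immediate early and dissociation stress genes 6 rose and 4 fell. Of 31 interferon response genes 2 fell, and Tap1 and Gbp2 varied between the AKG libraries. The interferon count rested on AKG 3: without AKG replicate 3, 11 were lower and 1 higher (median -0.35), and with AKG 2 alone 13 were lower and 1 higher (median -0.49). Of 36 cytosolic ribosomal protein genes 5 rose and 3 fell, and of 19 clock genes 6 rose and 7 fell. Their camera adjusted p was 0.619, 0.822, 0.812, 0.259, 0.619, 0.933, 0.933 and 0.458 in this order. With total counts as the scaling 34 ribosomal protein genes were higher and 0 lower, and 11 clock genes were higher and 3 lower. The hypoxia list then had 10 higher and 5 lower, the matrix list 18 and 5, the stress response list 8 and 2, the NRF2 list 6 and 3 and the immediate early list 13 and 2. For the hypoxia, matrix, interferon and ribosomal lists the median and the test differed in sign. By camera 13 of the 31 lists passed in all, and 0 with an estimated correlation.

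By the authors' deposited false discovery rate 5884 genes were under 0.05, 3599 of them higher and 2285 lower by the deposited FPKM ratio. Of the 6590 genes called here, 5049 (76.6%) were also called in the authors' deposited table with the same sign. A further 649 were called in both with opposite signs, and all of these were higher by the FPKM ratio of the authors' deposited table and lower here, the direction of the 1.36-fold shift between the scales. The deposited false discovery rate did not always follow that ratio. It was 1.46e-11 for Ttn at a deposited log2 fold change of 0.00958, and 0.972 for Pln at 0.546. Opposite signs of the ratio therefore need not mean that the 2 tests disagreed. For Myh7 the authors' deposited table gave a log2 fold change of 6.70 beside 6.34 here.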

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

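Leaving out each library in turn gave 2751 to 3296 higher and 2845 to 3243 lower genes and 13 to 16 gene lists. The tests with covariates, with AKG 2 alone, with total counts and without mitochondrially encoded genes were chosen after the data had been seen. Higher genes numbered 6732 and 6725 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), 7431 with total counts, 2158 with the atrial covariate and 616 at a log2 fold change of at least 1. Lower genes numbered 1068, 1067, 1196 and 803 under the same settings, without the covariate. The FPKM and total-count settings follow the total of each library, from which the mitochondrial share fell. Why fewer genes passed with the atrial covariate was not tested. Between 3028 and 3391 higher genes were found with the other scalings and filters and with DESeq2 and limma-voom, and 3062 with upper quartile factors. AKG 2 alone, assumed to vary like the Controls, gave 2728 higher and 2800 lower genes. The replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.161, -0.0342 and 0.0489, the own number best for 1 of 3). The replicate block gave 3257 higher and 3314 lower genes, added 3 of 149 named genes and the atrial list (0.047), and took away the fatty acid list (0.0716). Of the 31 lists, 0 passed with an estimated correlation and 21 with fry. Of the called genes, 1956 were also called by the authors at a log2 fold change of at least 1.

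Without mitochondrially encoded genes in the total, the AKG over Control ratio of the count share was 1.05 for endothelial (1.26 with them), 0.786 for smooth muscle (0.942), 1.03 for Schwann cell, neuronal, adipocyte and mesothelial markers (1.24) and 0.597 for adult sarcomere genes (0.716). It was 1.04 for fibroblast (1.25), 0.639 for macrophage (0.768) and 4.55 for atrial markers (5.49), so the summed fibroblast share was not lower although 9 of its markers fell. The named genes and lists whose test turned direction had not passed it at first, unlike the 649 genes with opposite signs in the authors' deposited table. With total counts the medians, but not the test, of the fatty acid, fibroblast and smooth muscle lists turned to 0.07. Bpgm had a log2 fold change of -0.1614 to 0.00703 when single libraries were left out (above 0 without AKG replicate 3), 0.4459 and 0.4929 on log2 FPKM and 0.3444 with total counts, where it passed as higher (adjusted p = 0.00868 and 0.00846 by limma and 0.0173 by edgeR's quasi-likelihood test). The camera direction turned for lists that had not passed, here with the adjusted p. Total counts turned the matrix (0.639) and endothelial (0.68) lists. The endothelial list also turned with the atrial covariate (0.616) and with AKG 2 alone (0.497). The interferon list turned with upper quartile factors (0.997) and robust=FALSE (0.99), and the ribosomal list with upper quartile factors (0.997) and fry (0.898). Leaving out single libraries turned the hypoxia (0.469 to 0.884), matrix (0.489 to 0.981), endothelial (0.304 to 0.921), interferon (0.108 to 0.974) and ribosomal (0.355 to 0.907) lists in 1 or more of the 6 cases. Among them were 0.562 and 0.883 for interferon, 0.735, 0.776 and 0.876 for ribosomal and 0.776 for matrix genes.

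Other lists crossed the threshold of 0.05. With an estimated correlation the adjusted p was 0.554 for G2/M and tricarboxylic acid cycle genes, 0.38 for oxidative phosphorylation, sarcomere and fetal genes and 0.515 for mitochondrially encoded and neutrophil genes. It was 0.58 for fatty acid oxidation, fibroblast and macrophage genes, 0.492 for glycolysis and YAP genes and 0.548 for smooth muscle genes. Total counts gave 0.0156 for S phase, 0.507 for fatty acid, 0.0572 for smooth muscle, 0.00719 for lymphocyte and 0.0839 for neutrophil genes. The atrial covariate gave 0.0785 for fatty acid and 0.0584 for smooth muscle genes, the Y-linked covariate 0.0329 for S phase genes, and AKG 2 alone 0.0144 for interferon genes. Fry gave 0.0117 for S phase, 0.00934 for G1, 0.00726 for Polycomb, 0.0162 for integrated stress, 0.00638 for NRF2, 0.00677 for lymphocyte, 0.0452 for atrial and 0.00783 for clock genes. Without the low-count filter G1 (0.0492) and atrial (0.0438) genes passed, with the stricter filter lymphocyte genes (0.0453) and with robust=FALSE atrial genes (0.0273). Leaving out single libraries gave 0.0443 to 0.225 for S phase, 0.037 to 0.106 for G1, 0.0111 to 0.0825 for fatty acid, 0.0386 to 0.222 for lymphocyte and 6.85e-10 to 0.206 for atrial genes. The cause was not tested.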

Other observations

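The tests of atrial tissue, of scaling, of marker lists, of neutrophil precursors and of sex for the fetal genes were chosen after their results had been seen, and the tests of maturation, of length and GC content, and of sex for the G2/M genes were written before. The imprinted and glucocorticoid lists below were also put together after values of some members had been seen. Imprinted genes of the fetal growth network were higher after AKG. Of 14 tested, 11 rose and 1 (Impact) fell, with a median log2 fold change of 1.23, and Cdkn1c and Ndn did not pass. Plagl1 went from 40.7 ± 6.37 to 247 ± 27.9 CPM, Peg3 from 102 ± 4.22 to 284 ± 20.3 CPM and Zim1 from 2.89 ± 0.389 to 20.3 ± 5.03 CPM (mean ± SD over 3 libraries). Of 14 glucocorticoid receptor targets 5 rose and 0 fell, with Hif3a and Ddit4 (31.5 ± 5.71 to 69.4 ± 16.1 CPM) among those that rose. Their camera p was 0.00469, 0.4 with an estimated correlation, and 2.41e-25 as the smallest of the mixed splits, so the real split did not stand out. Fkbp5 stood at 8.90 ± 1.84 and 39.4 ± 30.2 CPM and did not pass. Fkbp5 and Hif3a varied widely between the AKG libraries, while Per1 (74.0 ± 7.69 CPM after AKG) and Errfi1 (35.4 ± 4.7 CPM) varied less.

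Of the 10 fetal list members that rose and are not on the atrial list, 8 stayed higher with the atrial covariate, so atrial tissue alone did not explain these. The median log2 fold change of the 10 was 1.46 beside 1.38 without it, and 1.48 with AKG 2 alone. The median of the whole list went from 0.53 to 0.07. Myl4, Myl7 and Mybphl are on this list and in the covariate, so part of that fall may have been set in advance. The covariate was 5.77 and 5.05 in AKG 1 and AKG 3 and 0.418 in AKG 2, so the adjusted changes leaned on AKG 2. Sex was argued against, since the median of the list was 0.514 with the Y-linked covariate, 9 of the 11 members that rose stayed higher, and Control 2, which lacked Y-linked transcripts, had 20.6 CPM of Myh7 beside 19.1 and 23.3 CPM in the other Controls. A candidate explanation is a less mature state of the heart muscle. On a list of growth genes that decline after birth, none of which had been looked at, 14 of 16 rose and 0 fell, with a median of 1.11 (camera p = 3.25e-11, 0.0406 with an estimated correlation, and 8.05e-09 as the smallest of the mixed splits). On a list of heart muscle genes that rise after birth 9 of 17 fell and 3 rose, with a median of -0.361 (camera p = 0.00522, 0.0923 with an estimated correlation, and 0.00728 as the smallest of the mixed splits). Neither list was tested with total counts as the scaling, where the median of all genes was 0.45. Whether AKG or a difference in age of the mice led to a less mature state stays open and was not tested.

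The fall of oxidative phosphorylation transcripts was not matched by length, GC content or expression: 0 of 10000 sets of matched genes had a median as low as -1.04, and their lowest was -0.724. Their mean was -0.279. Only the 44 list members were kept out of these sets, so other mitochondrial genes that fell could be drawn. That mean therefore does not show a fall by length, GC content or expression. Scaling moved the median to -0.594 at most. Without mitochondrially encoded genes it stayed at -1.04, but that setting hardly changed the scaling and so tested little. The median log2 fold change of all genes was then 0.00246 beside 0.00292. Whether the AKG libraries held a lower share of heart muscle cells could not be decided from markers, since the other cell types may also change among themselves. Their markers did not move alike: the endothelial and macrophage medians lay 0.649 apart (bootstrap interval over genes 0.405 to 1.01). With total counts as the scaling these medians were 0.341 and -0.3. The gap was 0.428 to 0.974 when single libraries were left out, which the bootstrap does not cover, and 0.565 to 0.694 over the scalings. Whether AKG or a difference in age of the mice led to the fall stays open and was not tested.

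The rise of G2/M genes was not matched by fibroblast, endothelial, smooth muscle or macrophage markers, since the G2/M median lay 0.925 above the highest of these 4 medians (bootstrap interval over genes 0.658 to 1.1, and 0.691 to 1.07 when single libraries were left out). With the Y-linked covariate the G2/M median was 0.692 beside 0.825, and 29 of the 33 genes stayed higher. With the atrial covariate 20 did and the list still passed camera, in a fit where higher calls over all genes fell from 3281 to 2158. The tested neutrophil and atrial markers had medians of 2.70 and 0.89, above the G2/M list. The tested neutrophil markers gained only 7.79 CPM in sum and the G2/M genes 351 CPM. Which cells divided, or whether cells stopped in G2 or M, may not be read from these libraries, and a part from atrial tissue and more division within stromal cells stay open.

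The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. Each mixed split sets 2 libraries of a group with 1 of the other, so it keeps part of the treatment difference and puts the rest into the spread, and it is no clean null for genes or lists. The real split was the only 1 of the 10 with as many higher genes (3281, against 0 in the highest other) or lower genes (3309, against 0). For gene lists 2 of the 10 splits gave as many, with 13 in the real split and 17 in the highest other. The G2/M list had a smaller adjusted p in another split (1.16e-18) than in the real one (1.34e-08), and 6 of the 13 called lists, oxidative phosphorylation and fetal cardiac genes among them, had their smallest p in the real split.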
